A study of Bos taurus with 15 samples.

How the data were processed

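Thymus RNA of 15 Holstein cows, 7 untreated and 8 given prednisolone at 30 mg per head daily for 35 days, was hybridised to 15 bovine oligonucleotide arrays (Agilent design 015354), 1 animal per array and 1 dye, per the labels. RNA was extracted with TRIzol and cleaned on RNeasy MinElute columns, per the labels' protocols. Groups follow the treatment label of each sample. The replicate numbers only follow the order of the samples.

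The scanner files hold the intensity of each spot as deposited, made with Feature Extraction 9.5.1.1, per the file headers. Their processed signal is background-subtracted, corrected for a multiplicative trend across the array and not scaled between arrays, per the file headers. The other columns used are flags of single spots (well above background, saturated, outlier), set by the scanner software, per the file headers. The authors also deposited a table of intensity values on a linear scale with 44396 rows, matched to the spots by spot number. The medians of its 15 columns lay between 188.5 and 274.1, and 5288 to 8740 cells per column were empty. Its rank correlation with the processed signal was at least 0.99963 on each array. The direction of its values is that of the signal, the scale is linear, and whether and how its columns were centred is unknown. The submitters' processing notes name R 2.11.1 and no normalization method.

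The log2 of the processed signal was centred on the 75th percentile of each array's bovine spots. Spots marked as outliers were then left out, and the other spots of a probe were averaged. The authors' values were taken to log2 and tested as deposited. Each array had 44407 spots, 42990 of them of the 21475 bovine probes, most with 2 spots. Symbols came from the gene number (9595 probes), accession (3502), description (2791) or gene name (394) in the files, matched to a list of cattle genes, and for 18 probes from the file's own name alone. No gene symbol was found for 5175 probes, 4812 without any match and 363 with only a locus number or clone name. Names by description rest on the human gene that the files call similar. Gene names that read as calendar entries in the scanner files were not used. Probes well above background on at least 7 of 15 arrays were kept, 16069 in all, for 11702 genes.

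Groups were compared with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0 and version 1.17.8 of data.table), with a Benjamini-Hochberg adjusted p under 0.05 over all kept probes as the threshold. Of the kept probes 67 had a value left out on some array, and 7 were never above background in 1 group. The 22 gene lists were fixed before the data were examined, as were the threshold, the filter and the alternatives given below unless said otherwise. They were tested with camera at the preset correlation of 0.01, using the brightest kept probe of a gene, and again with an estimated correlation and with fry. With the authors' values, the random block and trend and robust, cameraPR was used on the t statistics. The mean value of a list per animal was compared between groups by an exact permutation test over 6435 splits, and over the 64 arrangements that keep slides. Relations between lists were tested with 1e+05 permutations, so that 1e-05 is the smallest p they can give.

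Genes were named by a fixed rule: the 12 with the largest change in each direction among those that passed, or, where fewer than 5 passed, the 5 with the smallest p as values that did not pass. From each list up to 4 genes that passed over all kept probes were named, or the 2 with the smallest p where none passed. A gene that this rule names is not reported here, and the list tests were left as they were. The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' values, other filters, outlier spots kept, slide as a fixed or random block, eBayes with trend and robust, arrayWeights, the adipocyte score as a covariate, each animal left out, all probes of a gene averaged, and other list tests. All arrays were scanned on 1 day, so no alternative with the scan day was possible. Leaving out slide 4, with or without slide as a block, leaving out animals with testis or liver transcripts, and normexp without 12 spots of local background above 200 were added after the data were seen. So were list tests with an estimated correlation in 2 other fits, the 64 label arrangements within slides for counts of probes and lists, and the 11 lists of other tissues, of which 2 were drawn up from the values themselves.

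The calculation was tested on simulated data with 16002 probes, in 10 runs with 50 changed probes of each size. It found 50.8% of changes of 0.5 on the log2 scale, 81.6% of 1, 95.6% of 2 and 99.4% of 4, with 5.2% false among its calls. A simulated shift of 0.3 in 1 list was called in 10 of 10 runs, and other lists were called 2 times in all. The simulated values were drawn independently for each probe, without differences between slides. In the data the estimated correlation between members of a list went from 0.013 (T cell receptor genes) to 0.57 (erythroid genes). The simulated rates of list calls therefore do not carry over to the real lists. The number of arrays, 1 per animal, limits the precision. Tables were handled and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.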

Results

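Transcripts were measured in the thymus of 15 Holstein cows, collected at slaughter. The thymus is the organ in which T cells mature, and glucocorticoids are known to kill immature thymocytes and to shrink it. 8 cows had received prednisolone, a synthetic glucocorticoid, by mouth at 30 mg per head daily for 35 days, and 7 were untreated controls. RNA of 1 animal was labelled with 1 dye and hybridised to 1 bovine oligonucleotide array, so that a replicate is an animal. Each array held 21475 bovine probes, of which 16300 could be given a gene symbol, for 14676 distinct symbols. Between 67.1% and 77.7% of an array's bovine spots were well above background, and the number of arrays limits the precision. Values between pairs of arrays correlated with Pearson r from 0.967 to 0.991 across probes, which are not independent replicates.

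The arrays lay on 4 slides, which did not hold the groups evenly. Slide 1 held controls 1, 2 and 5 and prednisolone animal 6. Slide 2 held control 3 and prednisolone animals 3, 5 and 8. Slide 3 held controls 4, 6 and 7 and prednisolone animal 1. Slide 4 held only prednisolone animals 2, 4 and 7, so that a value within a slide could be had for slides 1 to 3, each with a single animal on 1 side. In the plot of the principal components the 3 arrays of slide 4 lay apart from the others. The first component held 42.5% of the variance, and slide accounted for 95.9% of its spread and treatment for 14.7%. The second component held 11.9%, with 84.1% of its spread between slides and 0.8% between treatments. Slide 4 differed from the other 5 prednisolone arrays at 2541 probes (548 higher, 1993 lower; limma, adjusted p under 0.05), and the 3 controls of slide 3 differed from the 3 controls of slide 1 at 988 probes (39 higher, 949 lower).

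**Figure D1:**
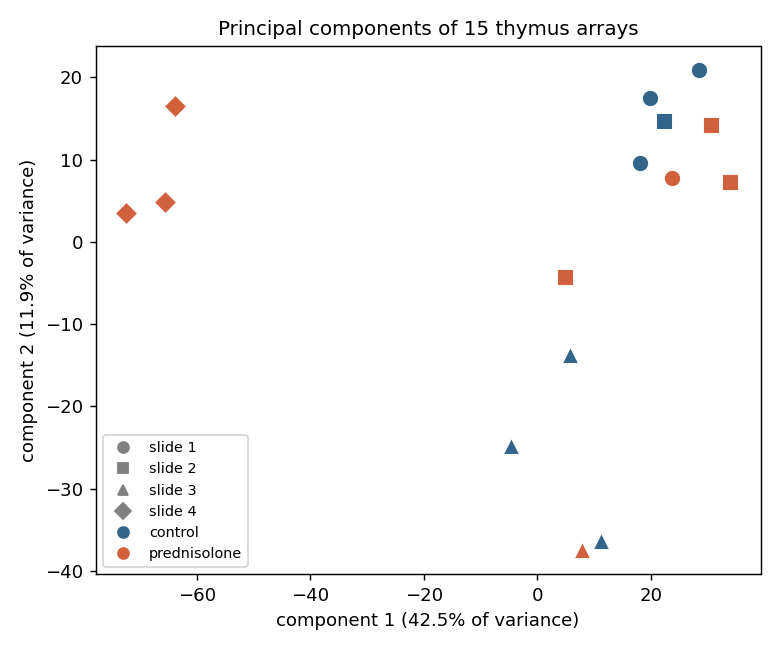
Each point is 1 animal's thymus array, placed by its first component (42.5% of variance, horizontal, arbitrary units) and second component (11.9%, vertical) over 16002 probes; colour gives the treatment and shape the slide. The 3 arrays of slide 4, all prednisolone, lie apart on the first component.

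The main comparison asks which thymus transcripts differ between cows given prednisolone and untreated cows. No gene passed the test in either direction. The smallest p-values among genes higher with prednisolone belonged to ARF1, a small GTPase of vesicle traffic (log2 difference, prednisolone minus control, 0.43 ± 0.083 SE), TAF6L (0.40 ± 0.083), ZC3H7B (0.47 ± 0.097), POLA2, a subunit of DNA polymerase alpha (0.69 ± 0.14), and RHBDF2 (0.44 ± 0.092), all with limma adjusted p = 0.378. Those among genes lower with prednisolone belonged to COX6A2, a subunit of cytochrome c oxidase (-0.69 ± 0.17, limma adjusted p = 0.418), UVRAG (-0.58 ± 0.14, 0.418), ITGA11 (-0.65 ± 0.17, 0.425), TIA1 (-0.25 ± 0.066, 0.464) and ACYP1 (-0.52 ± 0.14, 0.464). None of these 10 values passed. POLA2 was well above background on 1 of 7 control and 6 of 8 prednisolone arrays, and a second probe of TAF6L gave -0.20.

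Of 16069 probes kept, 0 were changed at an adjusted p under 0.05 with limma. At an unadjusted p under 0.05 there were 1138, of which 640 were higher and 498 lower with prednisolone, where 803 are expected by chance if slides do not differ. At least as many came from 20 of 100 splits of the 15 animals, the real one included. The smallest limma adjusted p was 0.236, and 274 probes differed by more than 1 on the log2 scale in either direction. Other scalings moved the split of the unadjusted count, to 719 higher and 720 lower with quantile normalization and to 547 higher and 650 lower with median centring. With slide as a fixed block limma also gave 0 changed probes, with 1537 at an unadjusted p under 0.05. Only 2 other settings gave any: quantile normalization 1 probe (ACYP1, -0.46, limma adjusted p = 0.0450), and leaving out prednisolone animal 1 gave 3 higher probes, among them TRADD (0.66, adjusted p = 0.0481).

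Genes that glucocorticoids are known to induce were mostly on the lower side in treated cows, without passing. Of 35 measured members, 11 were higher and 24 lower with prednisolone, and the median log2 difference was -0.15 (camera adjusted p = 0.106, with limma). The members with the smallest p were PIK3IP1, an inhibitor of PI3 kinase (0.27 ± 0.10), and SGK1, a kinase of salt transport (-0.23 ± 0.10), neither of which passed. The median was -0.14, -0.14 and 0.072 within slides 1, 2 and 3, and -0.12 with slide as a block, and -0.033 without slide 4. At the preset correlation the list passed with array weights, with the adipocyte score as a covariate and in 4 of 15 runs that left out 1 animal, against limma adjusted p = 0.769 with an estimated correlation over all 15 animals. The list of the glucocorticoid receptor and its partners had a median of 0.048 (12 of 19 higher, limma adjusted p = 0.288), which was -0.033 with slide as a block and 0.097, 0.023 and -0.038 within slides 1, 2 and 3. Its leading members were DAP3 (0.39 ± 0.12) and the co-repressor NCOR1 (0.29 ± 0.13), of which another probe gave -0.087.

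No T cell list passed. Genes of immature thymocytes had a median log2 difference of 0.038 (21 of 33 members higher, limma camera adjusted p = 0.292), with a mean log2 value per animal of 1.14 ± 0.042 in controls (SD) and 1.17 ± 0.056 with prednisolone (two-sided exact permutation p = 0.258). The leading members were CHRNA3 (0.28 ± 0.092, where a second probe gave -0.76) and TCF7, a transcription factor of early T cells (0.15 ± 0.085). T cell receptor and pan-T-cell genes had a median of 0.032 and a mean of -0.030, with 19 of 30 members higher (limma adjusted p = 0.605); its leading members were the co-receptor CD8A (0.23 ± 0.071) and RASGRP1 (0.31 ± 0.10). Mature and regulatory T cell genes had a median of -0.075 (17 of 23 lower, limma adjusted p = 0.129), led by the chemokine receptor CCR8 (-0.54 ± 0.27, above background on 6 of 7 control arrays) and the chemokine CCL5 (-0.42 ± 0.22). Within slides 1, 2 and 3 the immature thymocyte median was 0.025, 0.022 and 0.19, the T cell receptor median 0.076, 0.091 and 0.031 and the mature T cell median -0.054, 0.12 and -0.015. The same 3 lists had 0.059, 0.097 and -0.023 with slide as a block. None of the named members passed.

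Cell division genes had a median of -0.047, with 32 of 48 members lower (limma camera adjusted p = 0.0838), led by KIF2C, a kinesin of the mitotic spindle (-0.27 ± 0.11), and the spindle checkpoint gene MAD2L1 (-0.33 ± 0.16). With slide as a block the median was -0.067 and passed at the preset correlation (limma adjusted p = 0.044, and adjusted p = 0.989 with an estimated correlation). That call was lost in 7 of 12 runs that left out 1 animal, with a median of -0.014 without control 3. The median was -0.040, -0.14 and -0.034 within slides 1, 2 and 3. Apoptosis regulators had a median of 0.0084 and a mean of -0.041 (15 higher and 14 lower of 29, limma adjusted p = 0.769), 0.035, -0.043 and 0.012 within slides 1, 2 and 3, and 0.0003 with slide as a block. TRADD, an adaptor of the tumour necrosis factor receptor, was 0.56 ± 0.13 (limma adjusted p = 0.418 over all probes). It was the 1 member of any of the 22 lists that passed when adjusted over the list alone (limma adjusted p = 0.0221), and the other 21 lists had 0. BIK, which promotes cell death, was -0.32 ± 0.13 and did not pass.

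The fat and connective tissue lists were higher with prednisolone. Genes of adipocytes had a median log2 difference of 0.18, with 24 of 35 members higher (limma camera adjusted p = 0.0473 with the preset correlation, adjusted p = 0.769 with an estimated correlation). Its leading members were the lipase PNPLA2 (0.32 ± 0.12) and GPD1, an enzyme of glycerol metabolism (0.24 ± 0.094). Fibroblast and extracellular matrix genes had a median of 0.13, with 28 of 36 higher (limma adjusted p = 0.00879, and adjusted p = 0.769 with an estimated correlation). It was led by the growth factor receptor PDGFRB (0.36 ± 0.13) and PCOLCE, which enhances collagen processing (0.20 ± 0.085). No single member of either list passed. With slide as a block the medians were 0.34 (limma adjusted p = 6.47e-05) and 0.15 (0.018) at the preset correlation, and both lists had adjusted p = 0.717 with an estimated correlation. Within slides 1, 2 and 3 the adipocyte median was 0.24, -0.080 and 0.77, and the matrix median 0.25, 0.0001 and 0.15. The adipocyte value rested on prednisolone animal 1: without it the median was -0.030, and -0.0085 with slide as a block. The blocked matrix call was lost without controls 5 or 7 or prednisolone animals 1 or 6.

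Other structural lists did not pass. Thymic epithelium had a median of -0.011 (14 higher and 17 lower of 31, limma camera adjusted p = 0.605), led by CLDN7, a tight junction protein (-0.35 ± 0.15), and PRSS16, a protease of cortical epithelium (-0.14 ± 0.076). Endothelium had a median of 0.031 and a mean of -0.018 (14 of 25 higher, limma adjusted p = 0.953), led by FLT4 (-0.62 ± 0.22, above background on 4 of 7 and 4 of 8 arrays) and CLDN5 (-0.59 ± 0.25). Smooth and skeletal muscle genes had a median of 0.17 (19 of 21 higher, limma adjusted p = 0.0838), led by CALD1 (0.28 ± 0.099) and NEB (-0.38 ± 0.20, above background on 6 of 8 prednisolone arrays). Blocking by slide gave 0.019, 0.041 and -0.068 for these 3 lists. Within slides 1, 2 and 3 they were 0.097, 0.091 and -0.089 for epithelium, 0.073, -0.11 and 0.13 for endothelium and 0.84, 0.39 and -0.85 for muscle.

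Genes of macrophages and of red blood cells were lower with prednisolone. The macrophage list had a median of -0.13, with 28 of 31 members lower (limma camera adjusted p = 0.000799 with the preset correlation, adjusted p = 0.769 with an estimated correlation). HMOX1, which breaks down haem, was -0.43 ± 0.16, and SPIC, a transcription factor of iron-recycling macrophages, was -0.59 ± 0.29. The list of erythroid cells and blood had a median of -0.34, with 11 of 11 lower (limma adjusted p = 0.000986, and adjusted p = 0.769 with an estimated correlation). EPB42, a protein of the red cell membrane, was -0.32 ± 0.14, above background on 5 arrays of each group, and the platelet chemokine PPBP was -0.58 ± 0.29. None of these 4 genes passed. With slide as a block neither list passed: the macrophage median was -0.12 (limma adjusted p = 0.0649), and the erythroid median turned to 0.059 (0.861). Within slides 1, 2 and 3 the medians were -0.095, -0.13 and -0.077 for macrophages and -0.045, 0.17 and 0.13 for erythroid genes. Without the 3 arrays of slide 4 they were -0.046 and -0.13, and did not pass. The macrophage call was kept with slide as a random block (-0.15) and with slide blocked and slide 4 left out (-0.12), both at the preset correlation. The latter median had to equal that of the fixed block, since slide 4 holds no control, and only the error estimate differs.

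B cell and plasma cell genes were higher with prednisolone, with a median of 0.080 and 19 of 25 members higher (limma camera adjusted p = 0.0373, and adjusted p = 0.769 with an estimated correlation). BLNK, an adaptor of B cell receptor signalling, was 0.24 ± 0.10, the smallest p of the list, and did not pass. The median was 0.16, 0.32 and -0.054 within slides 1, 2 and 3 and 0.17 with slide as a block (limma adjusted p = 0.018, and adjusted p = 0.717 with an estimated correlation). The blocked call was lost without control 3, the only control of slide 2 (median 0.019, limma adjusted p = 0.309), and without prednisolone animal 5 (limma adjusted p = 0.0684). The other immune cell lists did not pass. Dendritic cell and antigen presentation genes had a median of 0.066 and a mean of -0.031 (18 of 29 higher, limma adjusted p = 0.496), led by the co-stimulator CD80 (-1.27 ± 0.56, above background on 5 of 8 prednisolone arrays) and BOLA-DMA (0.25 ± 0.14). Neutrophil genes had a median of -0.030 (16 of 23 lower, limma adjusted p = 0.956), led by ALOX5 (0.45 ± 0.24) and LTB4R (0.28 ± 0.16). Within slides 1, 2 and 3 the dendritic median was 0.13, 0.18 and -0.14 and the neutrophil median -0.64, 0.0008 and 0.073, and the blocked values were 0.10 and -0.084.

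Signalling lists and lists of neighbouring tissues did not pass either. Inflammatory mediators had a median of 0.085 (20 of 27 higher, limma camera adjusted p = 0.0838), led by the cytokines IL1A (0.83 ± 0.23, above background on 1 of 7 control and 7 of 8 prednisolone arrays) and IL1B (0.50 ± 0.18, on 6 of 7 and 8 of 8). Interferon-stimulated genes had a median of 0.055 (15 of 29 higher, limma adjusted p = 0.605), led by MX1 (0.53 ± 0.25) and PARP9 (0.17 ± 0.089). Immediate-early and heat-shock genes had a median of 0.020 and a mean of -0.0018 (19 of 34 higher, limma adjusted p = 0.769), led by IER2 (0.13 ± 0.074) and EGR2 (0.19 ± 0.12). Lymph node stroma and follicle genes had a median of 0.15 (7 of 9 higher, limma adjusted p = 0.245), led by PDPN (0.32 ± 0.14) and CXCL13 (-0.40 ± 0.26). Thyroid gland genes had a median of -0.039 and a mean of 0.14 over 5 members (limma adjusted p = 0.956), led by SLC26A4 (1.30 ± 0.51, above background on 2 of 7 and 7 of 8 arrays) and FOXE1 (-0.46 ± 0.33, on 7 of 7 and 6 of 8). In the order given, the blocked medians of these 5 lists were 0.13, -0.011, -0.028, 0.15 and 0.0021. Within slides 1, 2 and 3 they were 0.095, 0.18 and 0.037 for inflammatory, -0.15, 0.34 and 0.0069 for interferon and -0.0077, -0.071 and -0.15 for immediate-early genes, then 0.23, 0.11 and -0.12 for lymph node and -0.099, 0.25 and -0.065 for thyroid genes.

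Of the 22 lists, 5 passed camera with its preset correlation of 0.01, and 0 passed with an estimated correlation or with fry (all limma adjusted p at least 0.769 and 0.702). Comparing each list's mean value per animal between the groups by a two-sided exact permutation test over 6435 splits, the smallest p was 0.109 (erythroid; 0.729 after Benjamini-Hochberg adjustment over the 22 lists). With labels permuted only within slides, 64 arrangements, the smallest exact p was 0.0469 (B cells and plasma cells; 0.859 after the same adjustment). So few arrangements limit how small this p can be, and 1 list alone could not have passed after the adjustment over 22 lists. With normexp background correction only the erythroid call of the 5 was kept. The adipocyte, B cell and matrix medians were then -0.13, -0.40 and -0.25, but the median of all probes was -0.21, so that their sign says little. With 12 spots of local background above 200 left out, a step added after the data were seen, these medians were much smaller in size. The macrophage call was then kept as well, while the adipocyte and matrix calls were still lost. Part of the normexp result thus rests on those spots. Leaving out single animals ended the adipocyte, B cell and matrix calls, but neither the macrophage nor the erythroid call. The plot of list means per animal shows the spread between animals.

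**Figure D2:**
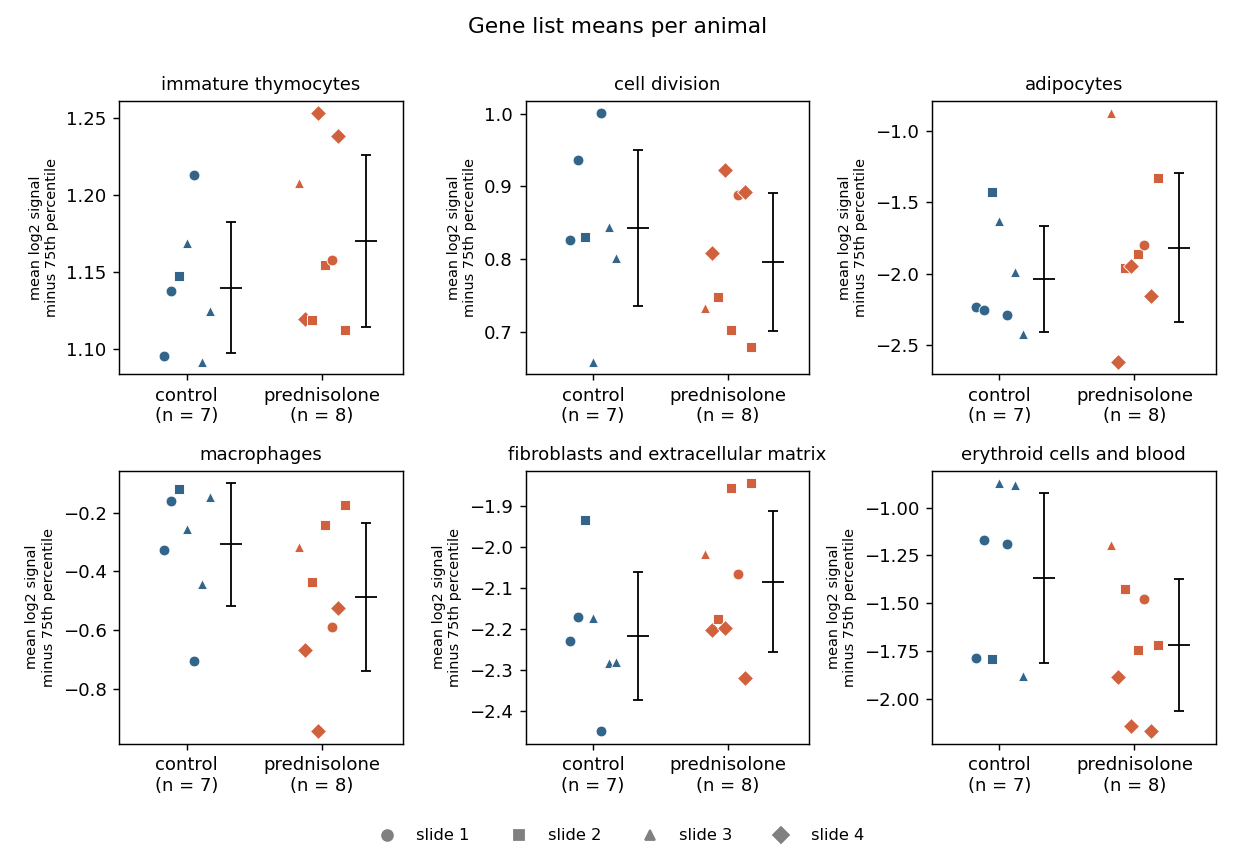
Mean log2 signal of a list's members minus the array's 75th percentile (vertical, log2 units) for 6 of the 22 lists, 1 point per animal, with the slide as the shape; horizontal ticks are group means and bars are 1 SD (7 control and 8 prednisolone animals). In every panel the groups overlap, and each exact permutation p is at least 0.109.

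**Figure D3:**
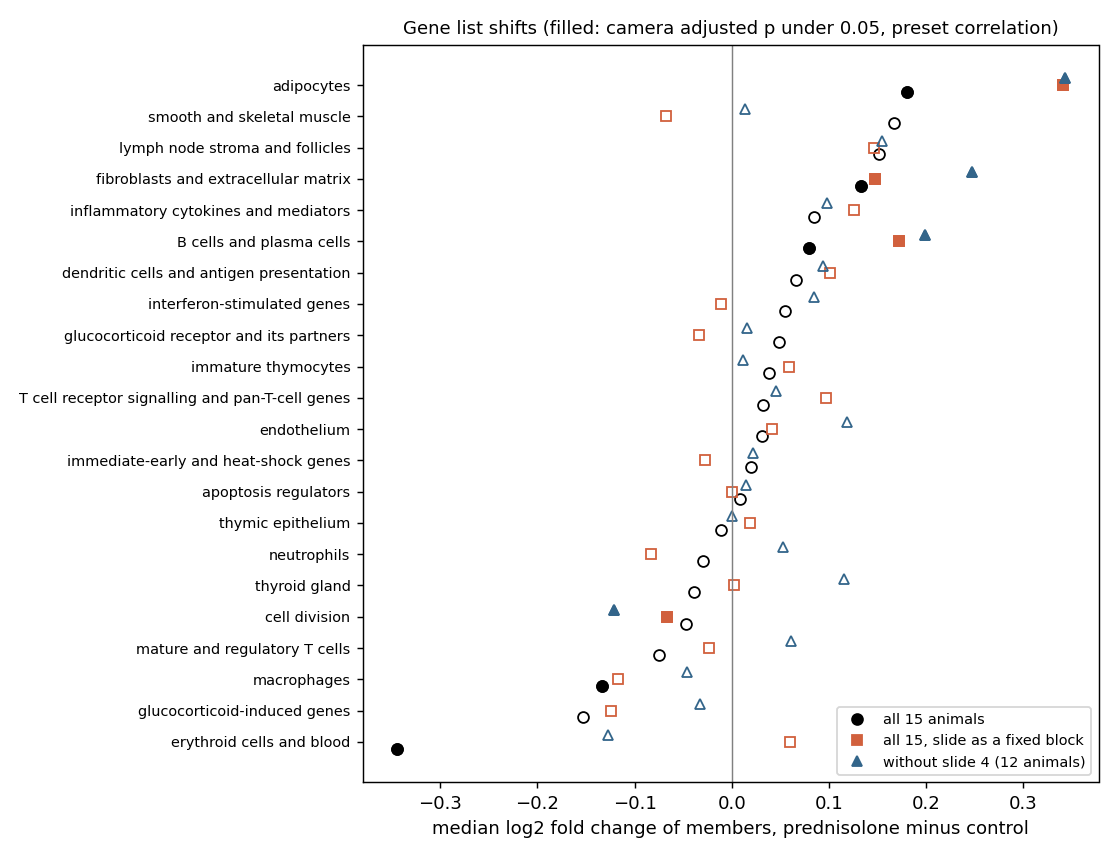
Median log2 difference of the members of each of the 22 lists, prednisolone minus control (horizontal, log2 units), with all 15 animals (circles), with slide as a fixed block (squares) and without slide 4 (triangles, 12 animals); filled symbols passed camera at the preset correlation. The erythroid median goes from -0.34 to 0.059 with the block, and the adipocyte median from 0.18 to 0.34.

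Lymphoid tissue and fat both make up the thymus, so the mean values of immature thymocyte and adipocyte genes were compared across animals. The adipocyte mean includes TF, which was high in prednisolone animals 3 and 4. Over 15 animals Pearson r was 0.18 (permutation p = 0.528) and Spearman rho 0.18 (p = 0.523). It was 0.12 within the 7 controls (permutation p = 0.815) and 0.11 within the 8 prednisolone animals (permutation p = 0.801), with rho of 0.036 (permutation p = 0.964) and -0.048 (permutation p = 0.935). Without the 2 animals farthest from the median adipocyte value, prednisolone 1 and 2, r was -0.11 (permutation p = 0.732), and without slide 4 it was 0.33 (permutation p = 0.294, rho 0.21). As deviations from the slide means r was 0.56 (permutation p = 0.0288, and 0.173 after Benjamini-Hochberg adjustment over the 6 relations of this family), with rho 0.50 (permutation p = 0.0598). Single slides held too few animals for a value.

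Transcripts that thymus is not known to make in quantity were high in single animals of either group. Genes of sperm cells, such as the protamine PRM1 that packs sperm DNA, lay above the median of the 15 animals by about 5.48 on the log2 scale in control 4, 4.19 in control 1, 2.73 in prednisolone animal 8 and 2.42 in control 6. Genes of the liver, such as the fibrinogen chain FGG and albumin (ALB), lay above it by about 5.93 in prednisolone animal 4 and 4.19 in prednisolone animal 3. On the scale of log2 signal minus the 75th percentile, PRM1 reached 4.37 in control 4 against -5.51 in control 2, and ALB 0.96 in prednisolone animal 4 against -7.83 in control 7. That ALB value of control 7 was not above background, and ALB was above it on 4 of 15 arrays. Since many of these genes were at background on most arrays, the distances from the median are at best lower bounds. All 11 liver genes were above background in prednisolone animals 3 and 4 and 2 to 9 elsewhere, and all 15 sperm-cell genes in controls 1, 4 and 6, 14 in prednisolone animal 8 and 4 to 11 elsewhere. Both lists were drawn up after these values were seen. Without these 6 animals, which left 4 controls and 5 prednisolone animals, limma gave 0 changed probes and 418 at an unadjusted p under 0.05. The erythroid call was then lost (median -0.19), while muscle (0.53) and cell division (-0.056) passed at the preset correlation. With an estimated correlation no list passed without these animals (all limma adjusted p at least 0.844).

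**Figure D4:**
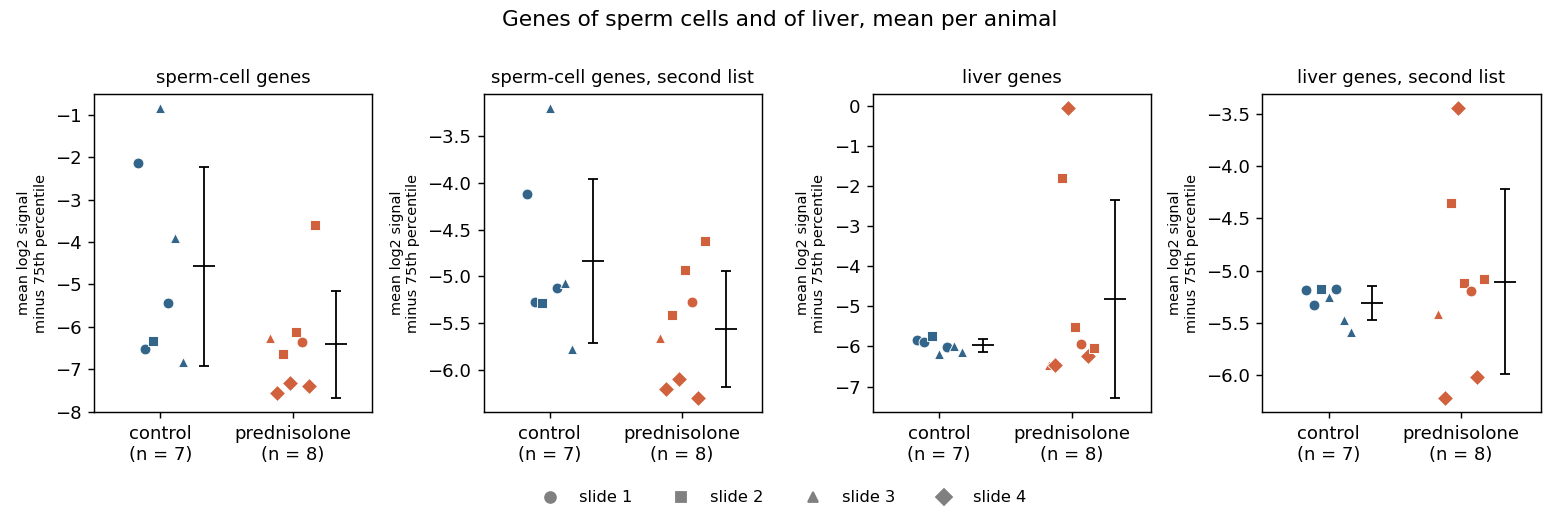
Mean log2 signal minus the array's 75th percentile (vertical, log2 units) over genes of sperm cells and of liver, each in a first list and in a second list drawn up without seeing its values, 1 point per animal; horizontal ticks are group means, bars 1 SD, and shapes the slides. Control 4 and prednisolone animal 4 are the highest for sperm-cell and liver genes in both lists.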

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

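The tests of slide 4 and of the fat genes and the arrangements within slides were chosen after the results were seen, and the spike-in slope was tested only after the dim spike-ins had not set slide 4 apart. Dixon's test was run on 150 groups of values, 44 of lists and 106 of genes, and singled out 11 of them at 1 in 20, 3 of lists and 8 of genes, where 7.5 are given by chance. These are its ratios.

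Among lists, the glucocorticoid receptor and its partners gave 0.613 (prednisolone animal 7, the highest of its group). Immediate-early and heat-shock genes gave 0.57 (control 6, highest) and 0.593 (prednisolone animal 7, highest). Among genes, TIA1 gave 0.57 (control 1, highest), DAP3 0.619 (control 1, lowest) and 0.538 (prednisolone animal 4, highest), and CHRNA3 0.576 (control 2, lowest). CCL5 gave 0.679 (control 6, lowest) and SPIC 0.598 (control 2, highest). PCOLCE gave 0.576 (control 3, highest) and EGR2 0.606 (control 5, highest).

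In 100 splits of the 15 animals, the real one included, all 100 gave at least the real 0 changed probes (highest other 2), which had to be so and decides nothing. A count as high as the real 1138 probes at an unadjusted p under 0.05 came from 20 of 100, with a highest other of 3298 in a split that kept the 3 arrays of slide 4 together, which points to the slides as a structure of the samples. The real split keeps them together too, and the other splits that did so gave from 509 to 3298. The real count lies within that range. As many lists as the real 5 passed in 61 of 100 splits (highest other 16). Chance is excluded for neither count, but these splits break up the slides. With slide as a block and labels rearranged only within slides, 2 of 64 arrangements, the real one included, gave as many as the real 1537 probes at an unadjusted p under 0.05 (highest other 1638). This share is under 1 in 20, but the count was chosen after the results were seen and is not adjusted. It rests on a single animal on 1 side of each slide and names no gene, so that chance is not excluded for it. As many lists as the real 4 passed in 53 of the 64 (highest other 13), so that chance is not excluded for the lists.

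Slide 4 stands apart from the other slides, and all its animals received prednisolone. If its processing is the cause, spike-in RNA should differ too: the 3 dimmest detected spike-ins differed by -0.54 in the mean, but the ranges of that mean overlapped (-3.70 to -3.24 against -3.39 to -2.59), although the dimmest of them alone lay lower on all 3 arrays (-5.78 at most against -5.41 at least), so that this test leaves it open. The spike-in slope was higher by 0.0595 (1.009 to 1.017 against 0.938 to 0.965), and 840 to 1049 spots were marked as non-uniform against 4 to 16 elsewhere, which suggests the slide's processing as a likely cause. If prednisolone were the cause, other animals should share the difference between slide 4 and the slide 1 controls. The median ratio of the 2 differences was -0.161 over 2990 probes, and 24.2% had the same sign. The other animals were prednisolone animals 1, 3, 5, 6 and 8 and controls 3, 4, 6 and 7. The former lay mostly on slide 2 and the latter mostly on slide 3, so that both values also carry differences between slides. With slide as a block the ratio was 0.046, which shows no shared difference. It rests on a single control of slide 2 and a single prednisolone animal of slide 3, so that this test cannot decide. Prednisolone animals of slide 4 may still differ for a reason of their own that these values do not show.

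Fat and matrix genes were higher with slide as a block at the preset correlation (limma adjusted p = 0.717 for both with an estimated correlation). A single animal may decide this, since the lowest adipocyte median with 1 animal left out was -0.01 (prednisolone animal 1), and the matrix median was then 0.095 and did not pass. A lower share of thymocytes could raise all other cells, but 5 of 8 lists of other cell types had a median above 0, which cannot tell. In the same fit the medians were 0.059 for immature thymocyte, 0.097 for T cell receptor and -0.023 for mature T cell genes. None of these lists passed, and no fall of immature thymocyte genes was seen. More fat in the tissue taken could raise fat genes as well: the 5 measured genes abundant in fat cells were all higher, FABP4 0.73 ± 0.79, PLIN1 1.03 ± 1.004, SCD 0.57 ± 0.39, LPL 0.92 ± 0.58 and FASN 0.31 ± 0.16 (± SE), while ADIPOQ was not among the kept probes. With errors of this size and 1 gene not measured, that test cannot tell either.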

How the results depend on the processing

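The 4 alternatives with slide 4, with animals holding testis or liver transcripts and with bright local background were chosen after the result was seen. No paired analysis was possible because the numbers only follow the order of the animals and pair no control with a treated cow. The count of changed probes was 0 in all settings but quantile normalization (1 probe, 1 lower) and leaving out prednisolone animal 1 (3 probes, 3 higher). The number at an unadjusted p under 0.05 was 1439 with quantile normalization, 1197 with median centring, 2987 with normexp (371 higher, 2616 lower), 1368 with the authors' values (690 higher, 678 lower), 1728 without a filter and 906 with probes above background on all arrays. It was 1136 with outlier spots kept, 1537 and 1111 with slide as a fixed and random block (correlation 0.373), 1142 with trend and robust, 1467 with array weights, 1788 with the adipocyte score, 1465 without slide 4, 1593 with the block added and 2016 with normexp without bright background. With normexp the median log2 difference of all probes was -0.21, so that its directions carry a shift of the whole array. The calls of lists gained or lost below use the preset correlation unless they name another test. With an estimated correlation, tried after the result was seen, 0 lists passed with slide as a fixed block and 0 without the animals with testis or liver transcripts. The relation of thymocyte and adipocyte genes was 0.36 with quantile normalization and 0.32 with normexp.

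Quantile normalization gained the call of cell division (-0.055), smooth and skeletal muscle (0.19) and inflammatory cytokines and mediators (0.16), and turned the direction of apoptosis regulators (-0.0006) and thyroid gland (0.0042). Median centring moved all lists up alike, with a median of all probes of 0.022, so that the value of thymic epithelium (0.011) above 0 shows no dependence of its own. Normexp background correction gained the call of immature thymocytes (0.11), dendritic cells and antigen presentation (0.063) and immediate-early and heat-shock genes (0.038), and lost the call of macrophages (-0.30), and turned the direction of cell division (0.002), apoptosis regulators (-0.16), adipocytes (-0.13), B cells and plasma cells (-0.40), fibroblasts and extracellular matrix (-0.25), endothelium (-0.28), smooth and skeletal muscle (-0.026), inflammatory cytokines and mediators (-0.36), interferon-stimulated genes (-0.072), TAF6L (-0.46), POLA2 (-0.75), RHBDF2 (-0.017), DAP3 (-0.53), PRSS16 (0.033), BLNK (-0.13), LTB4R (-0.31), PDGFRB (-0.54), PCOLCE (-0.10), SLC26A4 (-0.60), IL1A (-0.66) and IL1B (-0.57). The authors' values gained the call of cell division (-0.067), smooth and skeletal muscle (0.19) and inflammatory cytokines and mediators (0.16), and turned the direction of apoptosis regulators (-0.0072) and thyroid gland (0.038). Testing without a filter turned the direction of interferon-stimulated genes (-0.024). Keeping probes above background on all arrays gained the call of cell division (-0.052), and lost the call of adipocytes (0.12). Keeping outlier spots turned the direction of apoptosis regulators (-0.015). Slide as a fixed block gained the call of cell division (-0.067), and lost the call of macrophages (-0.12), and turned the direction of glucocorticoid receptor and its partners (-0.033), thymic epithelium (0.019), smooth and skeletal muscle (-0.068), erythroid cells and blood (0.059), thyroid gland (0.0021), interferon-stimulated genes (-0.011), immediate-early and heat-shock genes (-0.028), CCR8 (0.058) and FOXE1 (0.18). Slide as a random block lost the call of erythroid cells and blood (-0.16), and turned the direction of apoptosis regulators (-0.0067), interferon-stimulated genes (-0.013) and immediate-early and heat-shock genes (-0.014). Array weights gained the call of glucocorticoid-induced genes (-0.15), cell division (-0.075), dendritic cells and antigen presentation (0.16) and inflammatory cytokines and mediators (0.19), and turned the direction of apoptosis regulators (-0.029), thymic epithelium (0.020), thyroid gland (0.024) and immediate-early and heat-shock genes (-0.018). The adipocyte score as a covariate gained the call of glucocorticoid-induced genes (-0.17), and lost the call of B cells and plasma cells (0.13) and fibroblasts and extracellular matrix (0.065), and turned the direction of apoptosis regulators (-0.034), adipocytes (-0.024) and endothelium (-0.036). The adipocyte list was there adjusted for its own mean, so that its difference is removed by the setting itself. Leaving out slide 4 gained the call of cell division (-0.12), and lost the call of macrophages (-0.046) and erythroid cells and blood (-0.13), and turned the direction of mature and regulatory T cells (0.061), neutrophils (0.052), thyroid gland (0.12), LTB4R (-0.0056) and FOXE1 (0.16). Leaving out slide 4 and blocking by slide gained the call of cell division (-0.067), and turned the direction of glucocorticoid receptor and its partners (-0.033), thymic epithelium (0.019), smooth and skeletal muscle (-0.068), erythroid cells and blood (0.059), thyroid gland (0.0021), interferon-stimulated genes (-0.011), immediate-early and heat-shock genes (-0.028), CCR8 (0.058) and FOXE1 (0.18). These differences had to equal those of slide as a fixed block, since slide 4 holds no control. Only the error estimates differ, so that this setting is no separate test of direction. Normexp without spots of high local background lost the call of adipocytes (0.013) and fibroblasts and extracellular matrix (0.025), and turned the direction of T cell receptor signalling and pan-T-cell genes (-0.006), apoptosis regulators (-0.074), B cells and plasma cells (-0.026), dendritic cells and antigen presentation (-0.0067), endothelium (-0.051), inflammatory cytokines and mediators (-0.031), interferon-stimulated genes (-0.036), POLA2 (-0.068), PDGFRB (-0.022) and IL1A (-0.019). Leaving out animals with testis or liver transcripts gained the call of cell division (-0.056) and smooth and skeletal muscle (0.53), and lost the call of erythroid cells and blood (-0.19), and turned the direction of apoptosis regulators (-0.046), thymic epithelium (0.0077) and endothelium (-0.016). Averaging all probes of a gene gained the call of inflammatory cytokines and mediators (0.085), and turned the direction of apoptosis regulators (-0.013) and CHRNA3 (-0.24). Camera with an estimated correlation lost the call of adipocytes (0.18), B cells and plasma cells (0.080), macrophages (-0.13), fibroblasts and extracellular matrix (0.13) and erythroid cells and blood (-0.34). The test fry lost the call of adipocytes (0.18), B cells and plasma cells (0.080), macrophages (-0.13), fibroblasts and extracellular matrix (0.13) and erythroid cells and blood (-0.34).

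Leaving out each animal in turn gave 0 to 3 changed and 0 to 3 higher probes and 793 to 1420 at an unadjusted p under 0.05. Macrophage and erythroid calls were never lost this way. The adipocyte call was lost without controls 1, 2, 5 or 7 or prednisolone animals 1, 5, 6 or 8, the B cell call without controls 2 or 3 or prednisolone animals 3, 5 or 6, and the matrix call without control 5 or prednisolone animal 5. Calls were gained for glucocorticoid-induced genes (without controls 4, 5 or 7 or prednisolone animal 8), the receptor's partners and mature T cells (control 6), cell division (controls 1 or 4, prednisolone animals 2, 4 or 7), muscle (controls 1, 4 or 6, prednisolone animals 1 or 3) and inflammatory mediators (controls 4 or 7, prednisolone animal 4). TRADD passed without prednisolone animal 1 (0.66). Medians of the 22 lists over these runs went over the following ranges: adipocytes -0.030 to 0.24, apoptosis regulators -0.032 to 0.017, B cells and plasma cells 0.067 to 0.13, cell division -0.069 to -0.018, dendritic cells and antigen presentation 0.0021 to 0.10, endothelium -0.025 to 0.072, erythroid cells and blood -0.49 to -0.25, fibroblasts and extracellular matrix 0.084 to 0.19, glucocorticoid receptor and its partners -0.033 to 0.078, glucocorticoid-induced genes -0.17 to -0.066, immature thymocytes 0.016 to 0.056; immediate-early and heat-shock genes -0.045 to 0.046, inflammatory cytokines and mediators 0.048 to 0.16, interferon-stimulated genes -0.039 to 0.073, lymph node stroma and follicles 0.11 to 0.22, macrophages -0.19 to -0.088, mature and regulatory T cells -0.16 to -0.042, neutrophils -0.13 to 0.039, smooth and skeletal muscle 0.066 to 0.32, T cell receptor signalling and pan-T-cell genes -0.0003 to 0.055, thymic epithelium -0.053 to 0.030, thyroid gland -0.098 to 0.0041.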

Other observations

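The genes of this part were picked after the data were seen. Of well-known glucocorticoid targets, FKBP5, a co-chaperone of the receptor, was -0.33 ± 0.38 (SE; -1.07 ± 0.36 with slide as a block, limma adjusted p = 0.374) and TSC22D3 -0.58 ± 0.50 (-0.87 ± 0.54 with the block), a dim gene above background on 4 of 7 control and 3 of 8 prednisolone arrays. The clock gene PER1 was -0.22, the phosphatase DUSP1 0.16 and the receptor NR3C1 -0.069. None of these 5 passed.

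Some genes stood at 2 levels, more than 2 apart on the log2 scale with at least 3 animals at each, 111 in all. For 99 of them the levels parted slide 4 from the rest, and for 12 they did not. The serine proteases PRSS2 and KLK12 were high in the same 6 animals, controls 4, 5 and 6 and prednisolone animals 2, 4 and 5, with gaps of 3.64 and 3.61. IGFLR1, a receptor of the tumour necrosis factor family, was high in 2 controls and 5 prednisolone animals, and RET, a receptor tyrosine kinase, in 2 and 4. ZNF696 was high in 1 control and 6 prednisolone animals and AZI2 in 4 and 6. POLR1H was high in 4 and 2, BPIFB4 and MIC1 each in 5 and 7, TPRG1L in 5 and 4, TATDN2 in 5 and 3, and NTRK3 in 3 and 3. BOLA-NC1, of the major histocompatibility complex, had the largest SD within slides, 4.39.

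Sperm-cell and liver transcripts were high in single animals, as given above, and the series description calls the animals cows. If RNA of testis is the cause, a second sperm-cell list drawn up without seeing its values should follow the first: r was 0.9363 (permutation p = 1e-05, rho 0.936). It was 0.823 without controls 4 and 1 and 0.944 as deviations from slide means, and meiotic genes gave 0.724. Somatic testis genes gave 0.405 (permutation p = 0.134, rho 0.636), the same r as kidney genes. Their mean lay near the median of the 15 animals in controls 4 (-0.018), 1 (0.038) and 6 (0.015), and 0.35 above it in prednisolone animal 8. Somatic cells of the testis are thus not shown in those controls. The second liver list gave 0.8929 with the first (permutation p = 4e-05, rho 0.768). That r was 0.672 without prednisolone animals 4 and 3 and 0.944 as deviations, so that RNA of sperm cells and of liver may have reached these arrays. Thymic epithelium, known to transcribe genes of many tissues, could account for them too. The thymic epithelium list had r of 0.27 with the sperm-cell genes (permutation p = 0.326, rho 0.49) and 0.11 with the liver genes (permutation p = 0.694, rho 0.51). Its mean went only from -0.64 (prednisolone animal 7) to -0.30 (prednisolone animal 5). Sperm-cell and liver genes rose by up to 5.48 and 5.93 above their medians, which argues against a larger share of epithelium alone. AIRE, a member of that list, was not among the kept genes, and transcription per epithelial cell was not measured. 5 other tissues had a mean r of 0.073 with the sperm-cell and 0.063 with the liver genes. With the sperm-cell genes the 5 went from -0.47 (milk gland) to 0.40 (kidney), so that their mean says little. Those means hide that without prednisolone animals 4 and 3 the liver genes had r of 0.841 with kidney, 0.892 with pancreas, 0.866 with brain, 0.857 with intestine and 0.341 with milk gland genes (as slide deviations over all 15 animals 0.041, -0.22, 0.49, 0.065 and 0.019), and without controls 4 and 1 the sperm-cell genes 0.639 with kidney genes, so that the case for liver rests on those 2 animals.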
